A study of Homo sapiens with 12 samples.

How the data were processed

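RNA of 12 two-colour hybridisations to Agilent whole human genome arrays of 60-mer probes was measured, 1 clone and 1 control clone per array. Per the labels, 2 A2780s knockout clones were compared with control CA, 2 SKOV3 knockdown clones with control CS and 2 SKOV3 overexpression clones with control CSov, each clone on 2 arrays with exchanged dyes. The 3 manipulations were on 3 slides. The sample descriptions call the Cy5 RNA the reference on every array, whereas the channel labels put the clone in Cy5 on the array numbered 1 and in Cy3 on the array numbered 2. The channel labels were followed, and the log ratios of the 2 arrays of a clone, turned accordingly, correlated positively for all 6 clones, at r = 0.104 to 0.746 across genes. The study's design text names KOA1 for both knockout clones, and the sample titles were followed.

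The authors scanned the arrays and extracted spot values with Agilent Feature Extraction. The deposited scanner files hold each spot's mean signal and median local background as intensity, and the software's LogRatio, per the file headers, as log10 of processed red over green. The authors' notes give Feature Extraction 10.7.3.1, and the file headers give 10.5.1.1 on the 8 knockout and knockdown arrays and 10.7.3.1 on the 4 overexpression arrays. The deposited series values were log10 ratios of red over green, equal on 100% of spots to LogRatio at 3 significant digits, and not turned by dye. The deposited files of KOA1 and sh-S5 with the clone in Cy5 had been saved again at 3 significant digits.

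Each array had 45015 features, of which 1639 were controls, and 41000 distinct probes. A total of 31382 probes received a current gene symbol through the accession or name in the newer annotation grid of the arrays, or in the older one, and 9618 kept the name in the grid. Probe positions are those of the newer grid, in hg19. Sex-linked genes whose level could mark a person are not shown.

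Mean signals were background-corrected with normexp and an offset of 50 and normalised within arrays by loess in limma 3.58.1 under R 4.3.3, with control spots given no weight; values were handled with data.table version 1.17.8. Spots that the extraction software marked as irregular, 0.244% to 1.75% per array, were kept. Ratios were turned to clone over control, averaged over the spots of a probe, and the probe with the highest mean intensity stood for a gene. The 2 arrays of a clone were averaged to 1 replicate. A limma model with 1 coefficient per manipulation was fitted to the 6 clones, with 3 residual and 3.72 prior degrees of freedom, and the overexpression was contrasted with the knockdown and the knockdown with the knockout. A gene was tested where its probe was well above background in either RNA on at least 3 of the 4 arrays, and in both manipulations for a contrast. Tests were 2-sided, and p was adjusted by Benjamini and Hochberg within each comparison at 0.05.

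The comparisons, the 20 gene lists, the rule for naming genes and most alternatives were set before the data were examined. Named genes were the 8 largest rises and 8 largest falls per manipulation among genes past the threshold with 1 direction on all arrays, 5 each way per contrast, and 3 members per list. Lists with at least 5 tested members were compared with other genes by camera at a preset correlation of 0.01, adjusted over the lists of a comparison. No list passed with an estimated correlation. That test has only the 3 residual degrees of freedom, so a list can fail it for want of clones, whatever its correlation. The unfolded protein list of the overexpression had an estimated correlation of -0.023, under the preset 0.01. Its unadjusted camera p was still 1.1e-12 at the preset and 0.0039 with the estimate. Failing this test thus does not show that the members of a list move together. Beside camera, fry and camera on ranks were run. Of 20, 20, 19, 19 and 20 lists tested in the knockout, knockdown, overexpression and the 2 contrasts in the order above, fry passed 7, 11, 6, 7 and 10, ranks 1, 9, 7, 5 and 6, and fry for change in either direction 19, 18, 17, 18 and 20; fry asks whether the genes of a list move and does not compare them with other genes.

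The steps were tested on simulated data with 100 changed genes per size. A 2-fold change was called in 86% of genes in the knockout, 91% in the knockdown and 89% in the overexpression. Changed genes were drawn from probes brighter than the median, at levels averaged over all arrays and both dyes. The dim Cy5 channel of the overexpression slide was thus not simulated, and 89% does not give the sensitivity there. When the control clone was given the same spread as the clones, 67.6%, 66.6% and 62.0% of the calls were unchanged genes, against 4.64%, 2.05% and 6.40% without that spread. These shares depend on the small number of changed genes simulated: 424, 398 and 313 of 40400 unchanged genes were called. The difference arises since 1 control clone is shared by both clones of a manipulation and its spread does not enter the test.

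The alternatives were other background corrections, other normalisations, the software's own ratios, other filters and probe choices, fits on fewer clones or on arrays, single dye orientations, each clone left out, and other thresholds. Slide could not be a block, since each slide held 1 manipulation.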

Results

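RNA of 6 ovarian cancer cell clones labelled as altered in GRHL2 was hybridised against RNA of control clones on 12 two-colour 60-mer oligonucleotide arrays of the whole human genome. GRHL2, or grainyhead-like 2, is a transcription factor of epithelial cells. The knockout clones KOA1 and KOA2 were made with CRISPR/Cas9 in A2780s, labelled an ovarian endometrioid carcinoma line, and were set against control clone CA. In SKOV3, labelled an ovarian clear cell carcinoma line, the shRNA knockdown clones sh-S2 and sh-S5 were set against control clone CS, and the overexpressing clones OV1 and OV2 against control clone CSov. Each clone was on 2 arrays with the dyes exchanged, so a comparison rests on 4 arrays, 2 clones and 1 control clone, and errors below are for n = 2 clones. The number of arrays limits the precision of every value. The labels do not say whether the RNA of the arrays came from separate cultures, so the tests hold for these samples only. The spread in the tests is that between the means of the 2 clones, pooled over the manipulations. The 2 arrays of a clone were averaged before the main fit. The gap between its dye orientations thus enters no SE or p of that fit, and a small SE can go with a large gap.

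Median Cy5 signal was 6.91 to 17.1 times its local background on the 8 arrays of the knockout and knockdown and 1.16 to 1.21 times on the 4 arrays of the overexpression. Median Cy3 signal was 9.08 to 26.5 times background on the 12 arrays. Genes that could be tested numbered 28314 in the knockout, 25379 in the knockdown and 13804 in the overexpression.

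**Figure D1:**
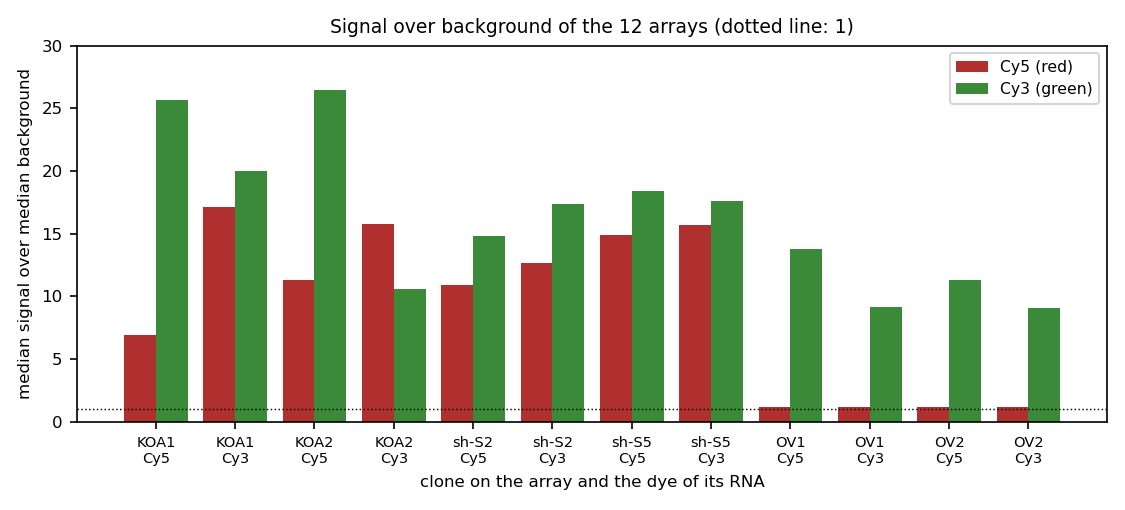
Median spot signal over median local background (vertical axis, ratio) in the Cy5 and Cy3 channels of each of the 12 arrays, with the clone and the dye of its RNA on the horizontal axis. The 4 overexpression arrays had Cy5 ratios of 1.16 to 1.21, against 6.91 to 17.1 on the 8 other arrays.

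GRHL2 itself was read by 1 probe, A_24_P35228, at chromosome 8, 102681572 to 102681631 of hg19. Its log2 ratio of clone over control was -0.088 (SE 0.078) in the A2780s knockout, with an adjusted p of 0.434 and 4 array values of 0.28, -0.42, 0.11 and -0.32. The probe was well above background on 3 of the 4 knockout arrays in each RNA, on 1 of 4 in the SKOV3 knockdown and on 0 of 4 in the SKOV3 overexpression, and its mean log2 ratios there, which were not tested, were -0.020 and 0.040. The probe thus showed no fall in the knockdown and no rise in the overexpression, at signals near background. The labels give neither the edited part of the gene nor the extent of the overexpressed cDNA, and the manipulations are named below as the labels name them.

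The A2780s comparison asked which genes differ in clones labelled as GRHL2 knockout. The largest rises were in NR0B1, an orphan nuclear receptor, at a log2 ratio of 6.32 (SE 0.71, adjusted p = 0.00112), in COL1A2, a chain of type I collagen, at 5.01 (SE 0.21, adjusted p = 2.3e-05), and in TFPI2, an inhibitor of serine proteases, at 4.91 (SE 0.21, adjusted p = 2.6e-05). FLRT3, a transmembrane protein of cell adhesion and fibroblast growth factor signalling, fell by 5.16 on the log2 scale (SE 0.093, adjusted p = 9.6e-06). AMIGO2, a neuronal adhesion protein, changed by -5.15 (SE 0.18, adjusted p = 1.7e-05). Among the further rises were GNG11, a G protein gamma subunit (4.18), PCDH17, a protocadherin (4.09), TMX4 (3.94), NAV3 (3.89) and HS6ST2, a heparan sulfate sulfotransferase (3.66). The further falls were in MEX3D (-4.33), POU3F3, a neural transcription factor (-3.77), GPR153 (-3.70), PRR36 (-3.62), WNT6 (-3.60) and COX6A2, a subunit of cytochrome c oxidase (-3.45). By the naming rule, all 16 had 1 direction on the 4 arrays. The other probe of COL1A2 gave 0.47, that of GNG11 -0.0037, that of WNT6 -0.095 and that of HS6ST2 -0.33, a fall that passed the test. Other probes ranged from -0.65 to -0.20 for MEX3D and from 0.38 to 3.32 for TMX4. Those of TFPI2, PCDH17 and NAV3 gave 3.47, 3.30 and 1.14. Of 74 genes taken by the naming rule in the knockout, 41 had several tested probes, and 11 had a probe of opposite direction. In 3 of these genes such a probe passed the test.

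**Figure D2:**
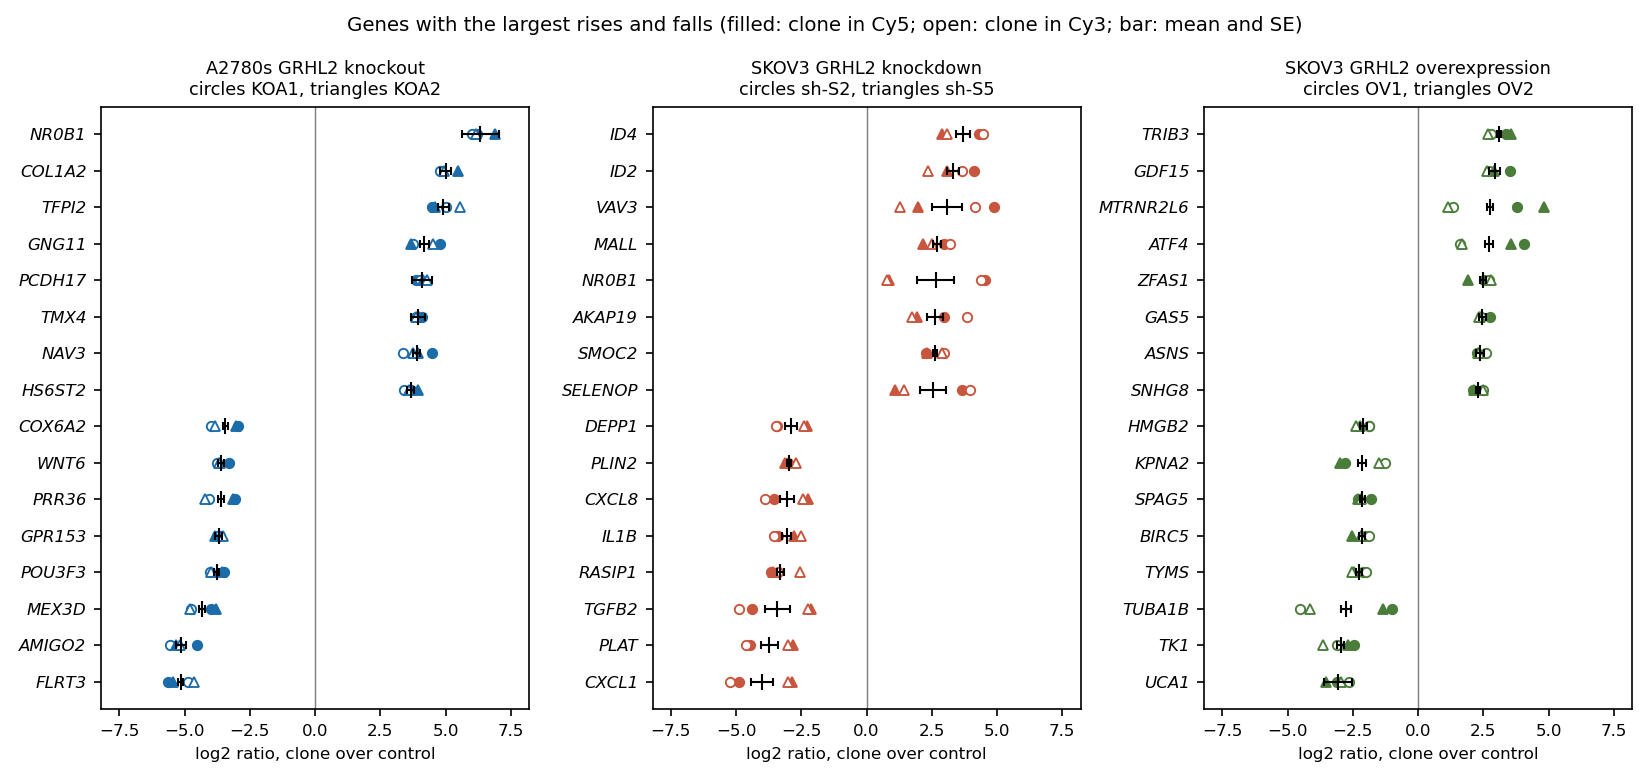
Log2 ratio of clone over control (horizontal axis) of the 8 genes with the largest rises and the 8 with the largest falls in each comparison, 1 gene per line; points are single arrays, and the black bar is the mean of the 2 clones with its standard error. By the naming rule, all points of a gene lie on 1 side of 0. Means in the knockout run from 6.32 for NR0B1 to -5.16 for FLRT3. The sh-S2 points of VAV3 and NR0B1 in the knockdown lie above those of sh-S5, and the Cy5 and Cy3 points of ATF4 and TUBA1B in the overexpression lie apart.

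Mesenchymal genes rose more often than they fell in the knockout. Of the 39 tested, 14 rose and 7 fell, or 15 and 7 adjusted over the list alone, and the list was higher than other genes at adjusted p = 0.0343, and adjusted p = 0.500 with an estimated correlation. On ranks it did not pass (adjusted p = 0.0740), nor with genes of opposite dye orientations left out (adjusted p = 0.0683). Nor did it pass with arrays centred on their median in place of loess. COL1A2, COL3A1 (3.05), both fibrillar collagen chains, and PDGFRB, a receptor of platelet-derived growth factor (1.62), rose, while S100A4, a calcium-binding protein of motile cells, changed by -1.90. Those 3 risen genes are also on the fibroblast marker list, which shares 9 of its 10 members with the mesenchymal list. Of the 10 fibroblast markers, 5 rose and 2 fell, the same numbers adjusted over the list alone (adjusted p = 0.0514). Matrix proteases and adhesion genes of the knockout counted 10 risen and 2 fallen of 40, the same numbers adjusted over the list alone, at adjusted p = 0.0514. MMP3, a stromelysin (1.29), and ITGB1, an integrin chain (1.27), rose, and TIMP1, an inhibitor of metalloproteases, fell by 0.94 on the log2 scale. Among 27 epithelial genes known as GRHL2 targets, 1 rose and 3 fell, or 0 and 3 adjusted over the list alone (adjusted p = 0.727). The 3 falls, in LSR, a protein of tricellular junctions (-0.72), LLGL2, a cell polarity protein (-0.36), and CLDN3, a claudin (-0.32), did not pass once a trend with probe GC content was removed, with -0.076 (adjusted p = 0.454), -0.15 (0.226) and 0.077 (0.462). The calls of LLGL2 and CLDN3 were also lost without KOA1 (adjusted p = 0.210 and 0.173) and without KOA2 (0.0737 and 0.101). Of 36 junction and keratin genes, 4 rose and 5 fell, the same numbers adjusted over the list alone (adjusted p = 0.685), with OCLN, a tight junction protein, at -1.79, DSC2, a desmosomal cadherin, at -0.90 and KRT18, a simple epithelial keratin, at 1.93. Other probes ranged from -1.86 to -1.72 for OCLN and from -0.028 to 2.21 for KRT18.

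The list of p53 targets and CDK inhibitors was also higher in the knockout. Of 35 tested members, 16 rose and 4 fell, or 17 and 5 adjusted over the list alone, and the list stood at adjusted p = 0.00851, and adjusted p = 0.500 with an estimated correlation. MDM2, which degrades p53, rose by 1.28 and FAS, a death receptor, by 0.74, while BBC3, a pro-apoptotic BH3 protein, changed by -2.60. Other probes ranged from -0.37 to 0.91 for MDM2 and from -0.15 to 0.93 for BBC3. For each of these 2 genes a probe of opposite direction passed the test, at -0.37 for MDM2 and 0.93 for BBC3. The direction of both thus depends on the probe. With genes of opposite dye orientations left out the p53 list had adjusted p = 0.0562. With arrays centred on their median in place of loess, neither the p53 nor the mesenchymal list kept its call, and 2 other lists were called. Without KOA2 the p53 list had adjusted p = 0.0513 and the mesenchymal list adjusted p = 0.0767. In fits on 12 arrays with the clone as a random block, the protease, interferon and fibroblast lists of the knockout, each at 0.0514 with clone means, passed at adjusted p = 0.0442, 0.0442 and 0.0410, and with the array number as a replicate block as well at 0.0421 each. Among apoptosis regulators, 2 rose and 8 fell of 32, the same numbers adjusted over the list alone (adjusted p = 0.528), with HRK, a BH3 protein, at -2.63 and XIAP, a caspase inhibitor, at -0.66. The other probes of HRK ranged from 0.031 to 0.32. Replication genes of G1/S counted 4 risen and 13 fallen of 44, and mitotic genes 6 and 10 of 47, in both lists the same numbers adjusted over the list alone (adjusted p = 0.516 and 0.685). Their medians turned with the dye, from -0.31 and -0.20 with the clone in Cy5 to 0.094 and 0.036 in Cy3. E2F2, a transcription factor of G1/S, changed by -0.80. KIF14, a mitotic kinesin, had 0.73, from 0.13 and -0.035 with the clone in Cy5 and 1.25 and 1.58 in Cy3, and XIAP had -1.15, -1.09, -0.42 and 0.012 in that order.

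Interferon-stimulated genes in the knockout counted 15 risen and 5 fallen of 45, or 18 and 6 adjusted over the list alone (adjusted p = 0.0514). DDX60 (1.21) and OAS3 (0.87) rose, and BST2, or tetherin, changed by -1.32. The other probes of DDX60, OAS3 and BST2 gave 1.86, -0.039 and -0.27. The ovarian and Mullerian lineage list had 6 rises and 4 falls among 32 genes, the same numbers adjusted over the list alone (adjusted p = 0.239), with HOXA9 at 2.91, HOXA11 at 0.91 and LIN28B, a repressor of let-7 microRNAs, at -1.01. The other probe of LIN28B gave 0.0071. Hypoxia and glycolysis genes rose in 8 and fell in 5 of 35 cases, or 12 and 6 adjusted over the list alone (adjusted p = 0.102), with SLC16A3, a lactate exporter, at 1.55. Cholesterol and lipid synthesis had 8 rises and 5 falls of 31, or 9 and 7 adjusted over the list alone (adjusted p = 0.570), and HMGCS1, an enzyme of the mevalonate pathway, rose by 1.04. In the unfolded protein and amino acid response, 7 of 32 genes rose and 3 fell, or 7 and 6 adjusted over the list alone (adjusted p = 0.685), with the chaperone HSPA5 at 1.31. Of the cytokines and NF-kB targets, 5 rose and 1 fell of 39, the same numbers adjusted over the list alone (adjusted p = 0.405), with PTGS2, an inducible prostaglandin synthase, at 1.73 and SOD2 at -1.08.

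TGF-beta and BMP targets counted 4 risen and 3 fallen of 31 in the knockout, or 3 and 3 adjusted over the list alone (adjusted p = 0.685), with ID3 at -0.85. For growth factor and MAPK output the counts were 6 and 3 of 46, or 4 and 3 adjusted over the list alone (adjusted p = 0.355), with the immediate early gene EGR1 at 1.88. The WNT pathway had 4 rises and 6 falls of 36, the same numbers adjusted over the list alone (adjusted p = 0.986), with the target gene SP5 at -2.14 and the secreted inhibitor WIF1 at 1.75. Other probes of SP5 ranged from -0.0056 to 0.24, and that of WIF1 gave 0.73. Neural genes had 1 rise and 2 falls of 32, or 1 and 1 adjusted over the list alone (adjusted p = 0.727), with SOX1 at -1.47 and its other probe at 0.21. Blood and endothelial markers had 1 rise and 1 fall of 20, the same numbers adjusted over the list alone (adjusted p = 0.528). The median, the mean and the test differed in sign for 3 lists, with a median of -0.0049, a mean of 0.026 and a test upward for the GRHL2 targets, 0.023, -0.055 and upward for the WNT pathway, and -0.0072, 0.012 and upward for the unfolded protein list.

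Across all genes of the knockout, 7718 of 28314 passed the test, 3618 higher and 4100 lower, and 386 and 614 of these had changed at least 2-fold. Housekeeping genes moved too, with TBP at -0.55 and HPRT1 at -0.49, which passed the test, and ACTB at 0.38 and GAPDH at 0.11, which did not. The log2 ratios of KOA1 and KOA2 correlated across genes at r = 0.905 (Spearman 0.800), and genes are not independent replicates. Simulated unchanged clones that share a control had r = 0.500, a value set by giving the control the spread of the clones. A control that differs more would raise r in unchanged clones, so the comparison does not show a change shared by the clones. The 2 dye orientations gave opposite mean directions for 753 of the called genes. The count was 2360 without KOA1, 3725 without KOA2 and 11942 without sh-S2 or without sh-S5, whose spread the test borrows. In this and the other comparisons with a control, 1 control clone served all arrays and its own spread was not in the test.

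The SKOV3 knockdown comparison asked which genes differ in clones labelled as GRHL2 knockdown by shRNA. The largest rises were in ID4, at a log2 ratio of 3.69 (SE 0.28, adjusted p = 0.00065), and ID2, at 3.31 (SE 0.23), both inhibitors of basic helix-loop-helix transcription factors. SMOC2, a matricellular protein, rose by 2.62 (SE 0.072, adjusted p = 7.0e-05), and MALL by 2.70 (SE 0.16). CXCL1, a neutrophil-attracting chemokine, changed by -4.00 (SE 0.42, adjusted p = 0.00156), PLAT, the tissue plasminogen activator, by -3.72 (SE 0.32), TGFB2, a TGF-beta ligand, by -3.42 (SE 0.48), and PLIN2, a coat protein of lipid droplets, by -2.98 (SE 0.071, adjusted p = 5.4e-05). The other large falls were in RASIP1 (-3.31), the cytokine IL1B (-3.05), the chemokine CXCL8 (-3.04) and DEPP1 (-2.90). Many of these changes were larger in sh-S2 than in sh-S5, with log2 ratios of 4.40 and 2.99 for ID4, 3.89 and 2.73 for ID2, -5.07 and -2.94 for CXCL1, -4.53 and -2.91 for PLAT and -4.66 and -2.18 for TGFB2. Further rises that differed between the clones were those of VAV3 at 3.08 (SE 0.56) with 4.90 and 4.15 on the arrays of sh-S2 and 1.98 and 1.28 on those of sh-S5, of SELENOP, a selenium carrier, at 2.55 (SE 0.50), of AKAP19 at 2.63 (SE 0.31) and of NR0B1 at 2.64 (SE 0.71, adjusted p = 0.0374). Control RNA gave NR0B1 signal well above background on only 2 of the 4 arrays, so the size of its rise is uncertain. The NR0B1 call was lost without KOA1 or KOA2 (adjusted p = 0.114) and without OV1 or OV2 (adjusted p = 0.0931), and that of SELENOP without KOA1 or KOA2 (adjusted p = 0.0558). A second probe of RASIP1 gave 0.0046.

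Replication genes rose more often than they fell in the knockdown, and 17 of 47 mitotic genes rose while 30 did not pass. Of 44 G1/S and replication genes, 28 rose and 2 fell, or 32 and 2 adjusted over the list alone, and the list was higher at adjusted p = 3.2e-12, and adjusted p = 0.317 with an estimated correlation. RRM2, a subunit of ribonucleotide reductase (1.72), POLA1, a DNA polymerase subunit (1.04), and DSCC1 (1.05) rose. Of 47 mitotic genes, 17 rose and 0 fell, or 19 and 0 adjusted over the list alone, and the list was higher at adjusted p = 0.00015, and adjusted p = 0.525 with an estimated correlation. CDK1, the mitotic kinase, rose by 1.15 and NDC80, a kinetochore protein, by 0.79. The mitotic list rested on sh-S5, since without it the list had a median of 0.054 and an adjusted p of 0.479. Interferon-stimulated genes counted 13 risen and 3 fallen of 44, or 16 and 3 adjusted over the list alone, and the list was higher at adjusted p = 0.00593, and adjusted p = 0.547 with an estimated correlation. IFI27 rose (0.95), whereas GBP1, an interferon-induced GTPase (-1.98), and ISG20, an exonuclease (-1.16), fell. Without sh-S2 the interferon list turned to a median of -0.024, with an adjusted p of 0.666.

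Cytokines and NF-kB targets fell more often than they rose in the knockdown, and 17 of 39 did not pass. Of 39 tested, 1 rose and 21 fell, or 1 and 22 adjusted over the list alone, and the list was lower at adjusted p = 4.3e-08, and adjusted p = 0.409 with an estimated correlation. CXCL1, CXCL8 and IL1B were joined by CXCL2 (-2.82) and IL1A (-2.62). LCN2, a siderophore-binding protein of the same list, rose by 1.55. LCN2 and the other genes called outside the naming rule were chosen after their values were seen. Hypoxia and glycolysis genes were lower as a list, with 5 risen and 17 fallen of 35, or 6 and 19 adjusted over the list alone. The test stood at adjusted p = 4.3e-05, and adjusted p = 0.273 with an estimated correlation. ADM, the vasodilator adrenomedullin (-1.97), BNIP3, a mitophagy receptor (-1.20), and ERO1A, an oxidoreductase of the endoplasmic reticulum (-0.81), fell. Cholesterol and lipid synthesis had 3 rises and 11 falls of 31, or 3 and 14 adjusted over the list alone, and was lower at adjusted p = 0.00155, and adjusted p = 0.281 with an estimated correlation. SQLE, squalene epoxidase (-1.21), fell, as did ABCA1, which exports cholesterol (-1.15), while SC5D, a late sterol enzyme, rose by 1.40. Other probes ranged from -0.17 to 0.017 for ABCA1 and from 1.01 to 1.61 for SC5D.

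Mesenchymal genes fell more often than they rose in the knockdown, with 2 risen and 12 fallen of 37, or 2 and 13 adjusted over the list alone. The list was lower at adjusted p = 0.00785, and adjusted p = 0.344 with an estimated correlation. ZEB2, a repressor of epithelial genes (-1.35), and CALD1, an actin-binding protein (-1.08), fell, and S100A4 rose by 1.02. The other tested probe of ZEB2 gave -0.086 and that of CALD1 -1.20. Matrix proteases and adhesion genes had 6 rises and 13 falls of 39, or 7 and 15 adjusted over the list alone, and were lower at adjusted p = 0.0230, and adjusted p = 0.317 with an estimated correlation. PLAT, the collagenase MMP13 (-2.17) and the lysosomal protease CTSB (-1.28) fell. GRHL2 targets of epithelial cells counted 5 risen and 1 fallen of 24, the same numbers adjusted over the list alone, and the list was higher at adjusted p = 0.0457, and adjusted p = 0.317 with an estimated correlation. MAL2, a protein of apical transport (2.23), and LSR (1.29) rose, and ELF3, an epithelial transcription factor, fell by 0.53 on the log2 scale. Junction and keratin genes counted 4 risen and 9 fallen of 34, the same numbers adjusted over the list alone (adjusted p = 0.343), with ITGB4, a hemidesmosomal integrin, at 1.23 and F11R, a junctional adhesion protein, at -0.85. Without sh-S5 the junction list had an adjusted p of 0.0389. On ranks the protease and GRHL2 target lists did not pass (adjusted p = 0.0706 and 0.0981). Without sh-S2 the mesenchymal, protease and GRHL2 target lists each had adjusted p = 0.0571, and the last also lost its call without KOA1 or KOA2 (0.0610) and without OV1 or OV2 (0.0550).

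Apoptosis regulators in the knockdown counted 2 risen and 10 fallen of 32, or 3 and 12 adjusted over the list alone, and the list was lower at adjusted p = 0.0230, and adjusted p = 0.317 with an estimated correlation. BID, a BH3 protein (-0.97), and the death receptor TNFRSF21 (-1.19) fell. In the unfolded protein and amino acid response, 3 rose and 11 fell of 32, the same numbers adjusted over the list alone, and the list was lower at adjusted p = 0.0457, and adjusted p = 0.317 with an estimated correlation. On ranks this list did not pass (adjusted p = 0.0924). HSPA5 (-1.39) fell and SLC7A11, a cystine transporter, rose by 1.42. The ovarian and Mullerian lineage list counted 4 risen and 2 fallen of 30, or 3 and 2 adjusted over the list alone, and was higher at adjusted p = 0.0329, and adjusted p = 0.317 with an estimated correlation. FOLR1, the folate receptor alpha (2.11), and CLU, or clusterin (0.91), rose. Without sh-S2 the adjusted p was 0.0571 for apoptosis regulators, 0.247 for the unfolded protein list and 0.133 for the ovarian list, and the unfolded protein list also lost its call without KOA1 or KOA2 (0.0610) and without OV1 or OV2 (0.0550).

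TGF-beta and BMP targets moved both ways in the knockdown. Of 30 tested, 8 rose and 6 fell, or 9 and 11 adjusted over the list alone (adjusted p = 0.830), with ID2, ID3 (1.67) and ID4 among the rises and TGFB2 among the falls. Growth factor and MAPK output counted 8 risen and 9 fallen of 46, or 9 and 11 adjusted over the list alone (adjusted p = 0.830), with IGFBP7 at 2.31 and VEGFC at -1.06. The WNT pathway had 6 rises and 4 falls of 32, or 7 and 4 adjusted over the list alone (adjusted p = 0.365), with the ligand WNT7A at 1.58. Among p53 targets and CDK inhibitors 6 rose and 4 fell of 34, or 7 and 4 adjusted over the list alone (adjusted p = 0.349), and the CDK inhibitors CDKN1B (0.74) and CDKN2D (0.90) were among the rises. Markers outside the lineage gave few calls, with 0 rises and 1 fall of 28 neural genes (adjusted p = 0.830), 0 and 2 of 9 fibroblast markers (adjusted p = 0.380) and 1 and 0 of 15 blood and endothelial markers (adjusted p = 0.753). Adjusted over the list alone, these were 0 and 1, 0 and 2, and 0 and 0. NRCAM, a neural adhesion protein, changed by -0.62 and DCN, the proteoglycan decorin, by -0.78. The signs of median, mean and test differed for the p53 list (0.069, -0.020, upward) and the blood list (-0.0012, 0.047, upward).

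In all, 6041 of 25379 genes of the knockdown passed the test, 2978 higher and 3063 lower, with 273 and 368 changed at least 2-fold. Of the housekeeping genes, ACTB (-0.66), GAPDH (0.59), YWHAZ (-0.54) and B2M (0.50) passed the test. The clones sh-S2 and sh-S5 correlated across genes at r = 0.605 (Spearman 0.541), and 66.0% of genes had the same sign in both. Simulated unchanged clones, with a control given the clones' spread, had r = 0.499 and 66.7%. Of the called genes, 145 had opposite mean directions in the 2 dye orientations. With the spread taken from the 2 knockdown clones alone, limma called 0 genes, with 5412 at an unadjusted p under 0.05, and with the 4 SKOV3 clones it called 3798.

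**Figure D3:**
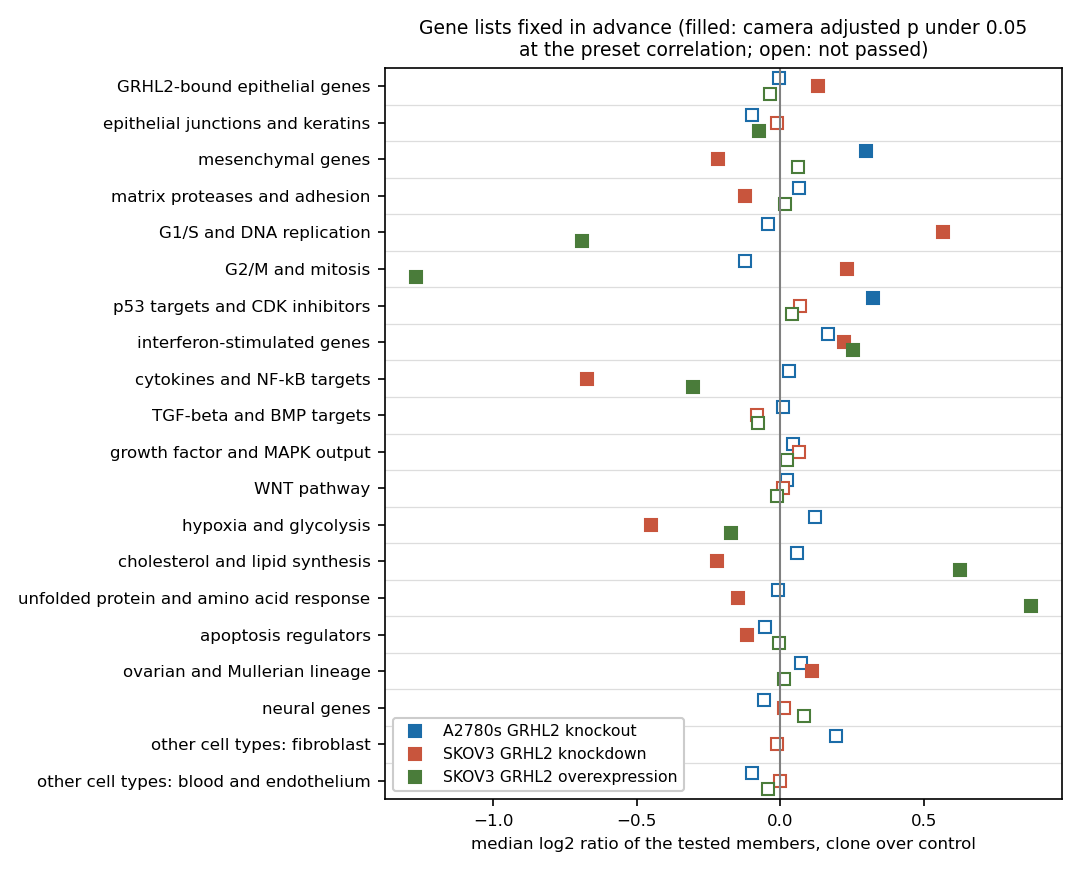
Median log2 ratio of clone over control (horizontal axis) of the tested members of each of the 20 fixed gene lists (vertical axis) in the 3 manipulations; filled squares passed camera's test at the preset correlation and open squares did not. The G2/M list lies at -1.27 in the overexpression and 0.23 in the knockdown, and the unfolded protein list at 0.87 and -0.15; with an estimated correlation no list passed.

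The overexpression comparison in SKOV3 asked which genes differ in clones labelled as overexpressing GRHL2. TRIB3, a pseudokinase induced by amino acid stress, rose 8.58-fold (log2 SE 0.088, adjusted p = 8.6e-05), GDF15, a stress-induced cytokine, by 2.94 (SE 0.21, adjusted p = 0.00045) on the log2 scale and ASNS, asparagine synthetase, by 2.37 (SE 0.14). GAS5 (2.47 (SE 0.12)), ZFAS1 (2.49 (SE 0.10)) and SNHG8 (2.30 (SE 0.071)), RNAs that carry small nucleolar RNAs in their introns, also rose. TK1, thymidine kinase of S phase, changed by -2.97 (SE 0.14, adjusted p = 0.00015), TYMS, thymidylate synthase, by -2.27 (SE 0.12), BIRC5, or survivin, by -2.16 (SE 0.11), SPAG5, a spindle protein, by -2.15 (SE 0.10), KPNA2, an importin, by -2.14 (SE 0.16) and HMGB2, a chromatin protein, by -2.10 (SE 0.14). Array values of some genes differed by dye, with ATF4, the transcription factor of the amino acid response, at 2.73 (SE 0.15) from 4.06 and 3.57 with the clone in Cy5 and 1.59 and 1.69 in Cy3, TUBA1B, a tubulin, at -2.77 (SE 0.19) from -1.02, -1.35, -4.53 and -4.16 in that order, and MTRNR2L6 at 2.77 (SE 0.12). The probe of MTRNR2L6 lies at 142375368 to 142375427 of chromosome 7 in the newer grid but at 2938 to 2997 of the mitochondrial chromosome in the older one, so its signal is not assigned to 1 of these. UCA1, a long noncoding RNA, changed by -3.06 (SE 0.54, adjusted p = 0.0110), and its call was lost at similar ratios without OV1 (-3.24, adjusted p = 0.130), without OV2 (-2.88, adjusted p = 0.188) and without KOA1 or KOA2 (-3.06, adjusted p = 0.0586). The other probe of TRIB3 gave 0.46.

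Most mitotic and replication genes fell in the overexpression clones, and 4 of 45 and 9 of 39 did not pass. Of 45 mitotic genes, 0 rose and 41 fell, or 0 and 43 adjusted over the list alone, and the list was lower at adjusted p = 2.7e-36, and adjusted p = 0.247 with an estimated correlation. BIRC5, NDC80 (-1.93), PBK, a mitotic kinase (-1.76), and PRC1, a protein of the central spindle (-1.62), fell. Of 39 G1/S and replication genes, 0 rose and 30 fell, or 0 and 33 adjusted over the list alone, and the list was lower at adjusted p = 3.4e-22, and adjusted p = 0.259 with an estimated correlation. TK1, TYMS and RRM2 (-1.88) were among them. The median of the mitotic list was -1.27, with -1.27 on arrays with the clone in Cy5 and -1.17 with the clone in Cy3.

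**Figure D4:**
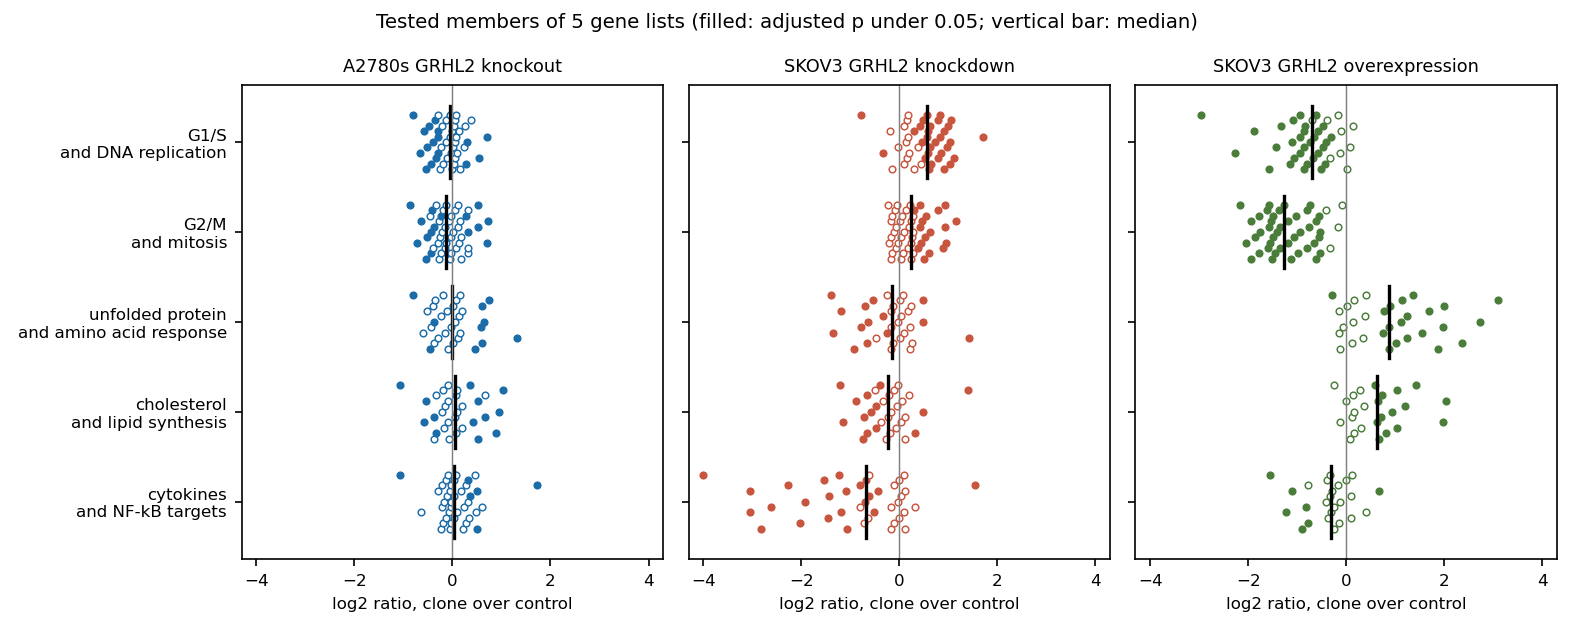
Log2 ratio of clone over control (horizontal axis) of every tested member of 5 fixed gene lists (vertical axis) in the 3 manipulations; filled points passed the test, open points did not, and the vertical bar is the median. In the overexpression 41 of 45 mitotic genes and 30 of 39 G1/S genes lie filled and below 0, and 19 of 31 unfolded protein genes and 14 of 25 cholesterol genes filled and above 0.

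Genes of the unfolded protein and amino acid response rose more often than they fell in the overexpression, 11 of 31 did not pass, and 10 had opposite directions in the 2 dye orientations. Of 31 tested, 19 rose and 1 fell, or 20 and 1 adjusted over the list alone, and the list was higher at adjusted p = 7.1e-12, and adjusted p = 0.0742 with an estimated correlation. TRIB3, ATF4 and ASNS were joined by NUPR1, a stress-induced chromatin protein (2.00), and HERPUD1, a protein of endoplasmic reticulum degradation (1.97). SDF2L1, a protein of the endoplasmic reticulum, fell by 0.29 on the log2 scale. For cholesterol and lipid synthesis, of 25 genes tested, 14 rose and 0 fell, or 16 and 1 adjusted over the list alone. The list was higher at adjusted p = 2.8e-09, and adjusted p = 0.191 with an estimated correlation, with SCD, stearoyl-CoA desaturase, at 1.96 and FADS1, a fatty acid desaturase, at 1.19. Other probes ranged from 0.42 to 0.63 for SCD, and that of FADS1 gave 1.30. Interferon-stimulated genes counted 11 risen and 0 fallen of 38, or 12 and 1 adjusted over the list alone. The list was higher at adjusted p = 0.00024, and adjusted p = 0.686 with an estimated correlation, with ISG15 at 1.71, IFI27 at 1.68 and IRF7, a transcription factor of the interferon response, at 0.99. Directions were opposite in the 2 dye orientations for 10 of the 38 interferon and 6 of the 25 cholesterol genes.

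Cytokines and NF-kB targets were lower in the overexpression, with 1 risen and 6 fallen of 25, or 1 and 7 adjusted over the list alone. The list stood at adjusted p = 0.00202, and adjusted p = 0.927 with an estimated correlation. NFKBIA, the inhibitor of NF-kB, was at -1.22 and SOD2 at -0.78, while RELB, an NF-kB subunit, rose by 0.66. The NFKBIA call was lost without OV1 (adjusted p = 0.0617) and without OV2 (0.0560), and that of SOD2 without OV1 (0.0553). Hypoxia and glycolysis genes counted 3 risen and 11 fallen of 31, or 5 and 13 adjusted over the list alone, and were lower at adjusted p = 0.00410, and adjusted p = 0.230 with an estimated correlation. LDHA, lactate dehydrogenase A (-1.42), and PGK1, phosphoglycerate kinase (-1.00), both glycolytic enzymes, fell, and DDIT4, an inhibitor of mTOR signalling, rose by 1.63. By dye, LDHA had -0.67 and -0.46 with the clone in Cy5 and -2.29 and -2.28 in Cy3, and DDIT4 2.84, 2.13, 0.65 and 0.88 in that order. Junction and keratin genes had 1 rise and 8 falls of 28, or 2 and 8 adjusted over the list alone, and were lower at adjusted p = 0.0186, and adjusted p = 0.262 with an estimated correlation, though on ranks at adjusted p = 0.0548. Of the 28 junction and keratin genes, 15 had opposite directions in the 2 dye orientations, as did 11 of 31 hypoxia and 6 of 25 cytokine genes. KRT19, a simple epithelial keratin (-1.41), and F11R (-1.02) fell, and OCLN rose by 0.28.

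The remaining lists of the overexpression did not pass. Epithelial GRHL2 targets had 0 rises and 1 fall of 15, the same numbers adjusted over the list alone (adjusted p = 0.257), the fall being that of MAL2 (-0.62), whose call was lost at the same ratio without OV1 (adjusted p = 0.179) and without OV2 (0.198). EPCAM, an epithelial adhesion protein, had -1.01 (adjusted p = 0.143, clone RNA well above background on 2 of 4 arrays) and PKP3, a plakophilin, -0.58 (adjusted p = 0.0925), and both passed at the same ratios without sh-S2 or sh-S5 (adjusted p = 2.0e-05 and 0.00130), whose spread the test borrows. Mesenchymal genes had 4 rises and 2 falls of 25, the same numbers adjusted over the list alone (adjusted p = 0.775), with FN1, or fibronectin, at 1.20, from 0.38 and 0.32 with the clone in Cy5 and 2.21 and 1.89 in Cy3, a call lost at similar ratios without OV1 (adjusted p = 0.137) and without OV2 (0.111), and S100A4 at -1.49, from -0.41 and -0.031 with the clone in Cy5 and -2.62 and -2.92 in Cy3. VIM, or vimentin, had -0.89 but lay at 0.84 and 0.94 with the clone in Cy5 and at -2.54 and -2.79 with the clone in Cy3. Proteases and adhesion genes had 2 rises and 1 fall of 28, the same numbers adjusted over the list alone (adjusted p = 0.981), with the hyaluronan receptor CD44 at -1.13 and the rises in CTSB (0.50) and ADAM17, a sheddase (0.41). Both rises were lost as calls without OV1 (adjusted p = 0.136 and 0.127) and without OV2 (0.112 and 0.268), that of ADAM17 also without KOA1 or KOA2 (0.0534), and ADAM17 had -0.19 with the clone in Cy5. The p53 and CDK inhibitor list counted 6 and 4 of 28, or 8 and 5 adjusted over the list alone (adjusted p = 0.923), with GDF15 risen and CDKN2D at -1.11. TGF-beta and BMP targets counted 2 and 4 of 20, or 4 and 4 adjusted over the list alone (adjusted p = 0.480), with ID1 at -1.74 and ID3 at -0.90.

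Growth factor and MAPK output had 2 rises and 3 falls of 25 in the overexpression, the same numbers adjusted over the list alone (adjusted p = 0.972). The WNT pathway had 2 and 2 of 16, or 2 and 3 adjusted over the list alone (adjusted p = 0.775), with DKK3 at 1.38, and WNT10A at -0.93 from -0.37 and -0.28 with the clone in Cy5 and -1.64 and -1.43 in Cy3. Apoptosis regulators had 1 and 2 of 27 (adjusted p = 0.972), the ovarian list 2 and 1 of 11 (adjusted p = 0.923), neural genes 0 and 1 of 14 (adjusted p = 0.775) and blood and endothelial markers 0 and 0 of 6 (adjusted p = 0.775), in all 4 the same numbers adjusted over the list alone. All 3 calls of the ovarian list turned with the dye, among them SPP1 to -0.34 with the clone in Cy5 and SOX17 to 0.17 with the clone in Cy3, and these were lost without OV1 (adjusted p = 0.107 and 0.174) and without OV2 (0.347 and 0.173). The other call was that of CD24, whose probe both grids place away from the gene, so its signal is not assigned to CD24. Fewer than 5 fibroblast markers could be tested. The signs of median, mean and test differed for the protease list (0.017, 0.036, downward), growth factor output (0.024, 0.026, downward), apoptosis regulators (-0.0058, 0.035, downward) and neural genes (0.081, -0.011, upward).

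Of all 13804 genes tested in the overexpression, 2328 passed, 1181 higher and 1147 lower, with 122 and 193 changed at least 2-fold. The log2 ratios of KPNA2, F11R, NFKBIA, ID1, ID3, DKK3 and HERPUD1 also differed by over 1.5 times between the dye orientations, with 1 direction on all arrays. TRIB3 had log2 ratios of 3.36 and 3.56 with the clone in Cy5 and 2.80 and 2.70 in Cy3, and TK1 -2.45, -2.70, -3.11 and -3.63 in that order. ACTB, at -1.23, had 0.0059 and 0.0027 on the arrays with the clone in Cy5 and -2.62 and -2.32 on those with it in Cy3, B2M rose by 1.34, and GAPDH changed by -0.41. The clones OV1 and OV2 correlated across genes at r = 0.872 (Spearman 0.712). Simulated unchanged clones, with a control given the clones' spread, had r = 0.499, and a control that differs more would raise it. Of all genes tested in the overexpression, 50.8% had opposite mean directions in the 2 dye orientations. Between the dye-swapped arrays of 1 clone r was 0.104 for OV1 and 0.172 for OV2, against 0.448 to 0.746 for the 4 other clones, and 359 of the called genes had opposite mean directions in the 2 dye orientations. The count was 588 without OV1, 379 without OV2, 1446 without KOA1 or KOA2 and 4214 without sh-S2 or sh-S5.

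The contrast of overexpression against knockdown asked where the SKOV3 clones labelled as overexpressing GRHL2 and those labelled as knockdown changed differently. TRIB3 differed most upward, by 4.29 (SE 0.12, adjusted p = 5.6e-05), having risen in the overexpression and changed by -1.19 in the knockdown, where its other probe gave 0.011. PLAT differed by 4.18 (SE 0.46), ATF4 by 3.66 (SE 0.21), TGFB2 by 3.66 (SE 0.68) and SPANXB1 by 3.27 (SE 0.35), with knockdown ratios of -3.72, -0.93, -3.42 and -1.90. The overexpression ratios of PLAT (0.45) and TGFB2 (0.24) did not pass on their own, and the TGFB2 difference was lost without OV1 (adjusted p = 0.0701) and without OV2 (0.0707). ID4 differed most downward, by -5.28 (SE 0.40, adjusted p = 0.00043), from -1.58 and 3.69, the first of which was lost as a call without OV1 (adjusted p = 0.149) and without OV2 (0.166). SMOC2 differed by -4.32 (SE 0.10), ID2 by -3.98 (SE 0.33), RRM2 by -3.59 (SE 0.15) and TK1 by -3.42 (SE 0.20), with overexpression ratios of -1.70, -0.68, -1.88 and -2.97. The overexpression ratio of ID2 and the knockdown ratio of TK1 (0.45) did not pass on their own.

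Between overexpression and knockdown, 6 of 19 lists passed the test. Mitotic genes differed in 42 of 45 cases downward and 0 upward, or 45 and 0 adjusted over the list alone, at adjusted p = 2.0e-24, and adjusted p = 0.396 with an estimated correlation. Replication genes differed in 34 of 39 downward and 1 upward, or 35 and 1 adjusted over the list alone, at adjusted p = 3.0e-19, and adjusted p = 0.396 with an estimated correlation. Epithelial GRHL2 targets had 4 downward and 0 upward of 15, or 3 and 0 adjusted over the list alone, at adjusted p = 0.0401, and adjusted p = 0.433 with an estimated correlation, though on ranks at adjusted p = 0.0616. The unfolded protein and amino acid response had 20 upward and 1 downward of 31, or 22 and 2 adjusted over the list alone, at adjusted p = 3.6e-09, and adjusted p = 0.110 with an estimated correlation. Cholesterol and lipid synthesis had 17 and 2 of 25, or 21 and 2 adjusted over the list alone, at adjusted p = 1.6e-08, and adjusted p = 0.216 with an estimated correlation. Cytokines and NF-kB targets had 11 and 1 of 25, or 13 and 1 adjusted over the list alone, at adjusted p = 0.00041, and adjusted p = 0.648 with an estimated correlation. In total 4065 of 13798 genes differed, 2039 upward and 2026 downward, of which 461 and 561 by at least 2-fold. The number was 1807 without OV1 and 1644 without OV2, and since each slide held 1 manipulation, slide and manipulation cannot be told apart here or in the next contrast.

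The contrast of knockdown against knockout asked where the SKOV3 clones labelled as knockdown and the A2780s clones labelled as knockout changed differently, and cell line, method, slide and control clone all differed between them. FLRT3 differed most upward, by 5.43 (SE 0.13, adjusted p = 3.7e-05), from 0.27 in the knockdown and -5.16 in the knockout. MEX3D differed by 5.23 (SE 0.14), AMIGO2 by 5.00 (SE 0.26), H2BC5, a histone gene, by 4.68 (SE 0.18) and POU3F3 by 4.67 (SE 0.15). TFPI2 differed most downward, by -5.91 (SE 0.30, adjusted p = 5.9e-05), from -1.00 and 4.91. NAV3 differed by -5.70 (SE 0.19), ADAMTS1, a secreted metalloprotease, by -4.90 (SE 0.62), COL1A2 by -4.73 (SE 0.29) and CXCL1 by -4.61 (SE 0.59). The knockdown ratios of FLRT3, AMIGO2 (-0.15), ADAMTS1 (-1.35) and COL1A2 (0.28) and the knockout ratio of CXCL1 (0.61) did not pass on their own.

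Of the 20 lists, 7 differed between knockdown and knockout. Mesenchymal genes were lower in the knockdown in 16 and higher in 4 of 37 cases, or 21 and 4 adjusted over the list alone, at adjusted p = 0.00021, and adjusted p = 0.322 with an estimated correlation. The fibroblast markers, mostly shared with that list, had 4 lower and 1 higher of 9, or 5 and 1 adjusted over the list alone, at adjusted p = 0.0493, and adjusted p = 0.322 with an estimated correlation, though on ranks at adjusted p = 0.114. Proteases and adhesion genes had 14 lower and 3 higher of 38, or 15 and 5 adjusted over the list alone, at adjusted p = 0.0131, and adjusted p = 0.322 with an estimated correlation. Cytokines and NF-kB targets had 16 and 1 of 38, or 17 and 2 adjusted over the list alone, at adjusted p = 4.6e-05, and adjusted p = 0.560 with an estimated correlation. Hypoxia and glycolysis genes had 15 and 2 of 35, or 16 and 3 adjusted over the list alone, at adjusted p = 0.00021, and adjusted p = 0.322 with an estimated correlation. Replication genes were higher in 26 and lower in 2 of 44, or 29 and 2 adjusted over the list alone, at adjusted p = 1.4e-06, and adjusted p = 0.557 with an estimated correlation. Mitotic genes were higher in 14 and lower in 3 of 47, or 17 and 3 adjusted over the list alone, at adjusted p = 0.00466, and adjusted p = 0.657 with an estimated correlation. In total 8067 of 25345 genes differed, 4302 upward and 3765 downward, of which 1334 and 1104 by at least 2-fold, and the number was 4042 without KOA1 and 5019 without KOA2.

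Called genes overlapped between manipulations more in opposite than in the same direction. The knockout and the knockdown called 2606 genes in common, of which 1788 had opposite directions and 818 the same, where independent lists would give 888.3 and 890.0, and their log2 ratios correlated across genes at r = -0.17. For knockdown and overexpression 684 were opposite and 406 the same, against 373.0 and 373.6 for independent lists. For knockout and overexpression 632 were opposite and 517 the same, against 440.5 and 439.1. Genes are not independent replicates, so no p is given for these numbers.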

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

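Among the tests below, those of a dye bias of the dim Cy5 channel and of reduced translation or growth, the dye gap under other background corrections, and the removal of the GC and brightness trends were chosen only after the result was seen.

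In 241 groups of 4 arrays, 9 held 1 array far from the other 3, where chance alone gives about 1 in 20 groups. LLGL2 in the knockout was -0.16 on the KOA2 array with the clone in Cy3 and -0.43 to -0.42 on the others, and MCM6 was 0.41 on the KOA1 array with the clone in Cy5 and 0.57 to 0.59 on the others. In the knockdown, MAL2 was 2.47 on the sh-S2 array with the clone in Cy3 (others 2.14 to 2.16), WNT7A 2.03 on the sh-S5 array with the clone in Cy5 (others 1.39 to 1.46), and NCAM1 1.09 on the sh-S5 array with the clone in Cy3 (others -0.032 to 0.11). In the overexpression, PGK1 was -1.07 on the OV1 array with the clone in Cy3 (others -0.98 to -0.97) and SCD 2.69 on the OV2 array with the clone in Cy5 (others 1.69 to 1.76). On the KOA1 array with the clone in Cy5, 79.6% of spots were well above background in red and 78.0% in green, against 97.6% to 98.8% and 98.0% to 98.3% on the other knockout arrays.

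The SKOV3 clones labelled as knockdown and the A2780s clones labelled as knockout differed in 8067 genes by the test of the difference, knockdown minus knockout, and cell line, method, slide and control clone cannot be told apart in it. List medians of this difference were -0.66 for mesenchymal genes, -0.20 for proteases and adhesion, 0.53 for G1/S and replication, 0.33 for mitosis, -0.77 for cytokines and NF-kB targets, -0.41 for hypoxia and glycolysis and -0.31 for fibroblast markers. The genes were FLRT3 (5.43), MEX3D (5.23), AMIGO2 (5.00), H2BC5 (4.68), POU3F3 (4.67), TFPI2 (-5.91), NAV3 (-5.70), ADAMTS1 (-4.90), COL1A2 (-4.73) and CXCL1 (-4.61).

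Knockout and knockdown called 2.01 times as many genes in opposite directions as independent lists give. Because the calls share 1 spread per gene, independent lists are not what unrelated manipulations would give. Log ratios followed probe GC content at r = -0.23 across genes in the knockout and 0.17 in the knockdown. With that trend removed the ratio was 1.97, so it does not explain the pattern as a whole. With a trend in spot brightness removed the ratio was 2.03. That removal could change little, because after loess the log ratios followed brightness at r = -0.077 in the knockout and -0.0011 in the knockdown. A difference of 1 control clone from the parental cells stays open, since the number of control clones per cell line on the 2 slides was 1. The cell lines and the methods of suppression also differed, and this was not tested.

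In the overexpression clones 41 of 45 mitotic and 30 of 39 replication genes fell, and 19 of 31 genes of the unfolded protein and amino acid response rose. With an estimated correlation, in a camera test with 3 residual degrees of freedom, the lists did not pass, at adjusted p = 0.247, 0.259 and 0.0742. The median of the mitotic list was -1.17 in the dye orientation with the smaller change, and -1.49 over the 29 members well above background in both RNAs on all arrays, which argues against the dim Cy5 channel as the cause. Reduced translation or growth of the overexpression cultures is a candidate explanation: the other snoRNA host genes, whose RNAs are degraded during translation, had a median of 0.75, at percentile 100 of random lists, and 9 of 14 rose while 0 fell by limma's test. The same genes, which may move together, had -0.63 at percentile 0.01 in the knockout, where 3 rose and 10 fell, so an extreme percentile is not particular to the overexpression. A difference of the control clone CSov from the parental cells cannot be told apart from it, since the number of control clones on the overexpression slide was 1, and an effect of GRHL2 itself also stays open.

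Log ratios of 1 overexpression clone differed between its dye-swapped arrays. The dye gap correlated across genes at r = 0.183 with that of the knockdown slide and 0.224 with that of the knockout slide, against 0.773 between those slides, so a bias shared by the 3 slides may carry a part. The gap of the brightest genes over that of the dimmest, by quartile, was 3.45, where a dim Cy5 signal was set down to give more gap in dim genes. That bound was not a fair one, because the offset of 50 draws dim ratios toward 0: with an offset of 0 the value was 0.973 and with the software's own ratios 0.635, while without background correction it was 3.01. Between the 2 overexpression clones, arrays of the same dye orientation correlated at r = 0.835 and 0.852, and those of opposite orientation at 0.193 and 0.107. The gap thus repeated in both clones. Dim Cy5 signal and a shared dye bias cannot be told apart, and neither was shown to account for the whole gap.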

How the results depend on the processing

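The fits without the overexpression slide, without the 2 re-saved arrays, with a dye term per manipulation, with the GC or brightness trend removed, and with opposite dye orientations left out were chosen only after the result was seen. Over 37 settings, values of named genes stayed on their side of the threshold in 6810 cases, weakened in 437, strengthened in 34 and reversed in 6. For list medians the numbers were 1630, 60, 36 and 1. Values that passed neither in the Results nor under the setting count among the 6810 and 1630 whatever their direction. Some settings leave the log2 ratio of a gene unchanged and so cannot reverse it, such as treat, another eBayes or leaving out a clone of another manipulation. The series matrix values nearly repeat the software's own ratios. The few reversals thus do not measure how stable the directions are. Called genes in knockout, knockdown, overexpression, overexpression against knockdown and knockdown against knockout numbered 7718, 6041, 2328, 4065 and 8067. Called lists in the first 3 were 2, 12 and 8. A count within 1.5 times can hide other members: median centring without loess ended both knockout calls and called 2 other lists. Of the 12 knockdown calls, 3 ended with the strict filter on dim probes and 3 with opposite dye orientations left out. Leaving out flagged spots, averaging all probes, a trended and robust eBayes and removing the GC trend each ended 2. So did the knockdown clones alone, the 4 SKOV3 clones alone and leaving out the overexpression slide. In the order given, with results that stayed within 1.5 times left out: normexp offset 0 gave 2711, 1489, 2470 and 3339 (all but overexpression) and 4 knockout lists; Agilent processed log ratio 3519, 2385, 3931 and 4179 (all but the first contrast) and 4 knockout lists; series matrix values 3524, 2385, 3931 and 4176 and 4 knockout lists; scale between arrays 3694 in knockout, 3819 in overexpression and 5 knockout lists. Only the 2 clones of the comparison gave 0 knockdown genes by limma (5412 at an unadjusted p under 0.05), 4424 overexpression genes and 4 knockout lists, and only the 4 SKOV3 clones 3798 and 1306. With 12 arrays, clone as random block gave 5 knockout lists, the replicate block 5, a dye term per manipulation 5, and arrays as if independent 5 and 1403 overexpression genes. Each of these fits, scaling between arrays and leaving out the re-saved arrays ended 1 of the 12 knockdown list calls. Only arrays with the clone in Cy5 gave 3809 overexpression genes, and only those in Cy3 1 knockout list. With the clone in Cy5 only, the calls of the p53 list in the knockout (adjusted p = 0.0504), the protease (0.0637) and interferon (0.0571) lists in the knockdown and the junction (0.177) and hypoxia (0.0693) lists in the overexpression ended, and the protease and G1/S lists of the knockout were called (both 0.0173). With the clone in Cy3 only, those of the mesenchymal list in the knockout (adjusted p = 0.203), the GRHL2 target (0.182), unfolded protein (0.159), apoptosis (0.0868) and ovarian (0.136) lists in the knockdown and the hypoxia list in the overexpression (0.0802) ended. An unadjusted p with 2-fold gave 1006, 691, 331, 1081 and 2493, and treat 912, 278, 201, 620 and 1710. Camera with estimated correlation gave 0, 0 and 0 lists (1, 2 and 3 unadjusted), fry 7 knockout lists and ranks 1. The knockdown clone correlation was 0.856 over called genes. Without the 2 re-saved arrays there were 4775, 3284, 1094, 2073 and 5107 genes, 1 knockout list and a knockout correlation of 0.739. The GC trend removed left 1 knockout list, and opposite dye orientations left out gave 2313 and 4963 in the contrasts and 0 knockout lists by camera (6 unadjusted). Without 1 clone, whose partner was assumed to vary like the other clones, counts ranged from 2360 (without KOA1) to 11942 (without sh-S2 or sh-S5) in knockout, 379 (without OV2) to 4214 (without sh-S2 or sh-S5) in overexpression, 1644 (without OV2) to 5606 and 4042 (without KOA1) to 10018 in the contrasts, and lists from 0 (without KOA2; 5 unadjusted by camera) to 4 in knockout and 5 (without sh-S2) to 12 in knockdown. Reversed were, in overexpression, VIM (0.89), ADAM17 (-0.19), SPP1 (-0.34) and CD24 (-0.12; its probe is placed away from the gene) with the clone in Cy5, SOX17 (0.17) with the clone in Cy3, in knockout CLDN3 (0.077) with GC removed, and the knockdown interferon median, from -0.024 (without sh-S2) to 0.46. Fewer clones, arrays or genes were in part the construction of these settings, and elsewhere the cause was not tested. Slide as a block could not be run, and Aquantile moved no ratio (0). Cy5 signal of 1.16 to 1.21 times background limited the genes tested in overexpression to 13804.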

Other observations

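All of the following 12 lists were chosen only after the result was seen, and their tests were adjusted over 35 tests; with an estimated correlation none passed, the smallest adjusted p being 0.161. In the overexpression, snoRNA host genes had a median of 0.87 (12 rose and 0 fell of 17, a list prompted by and including GAS5, ZFAS1 and SNHG8, without which the other 14 had 0.75 with 9 risen), against -0.64 in the knockout (3 and 15 of 19) and 0.12 in the knockdown (5 and 5 of 19). Replication-dependent histone genes had medians of -0.40, 0.69 and 0.070 in knockout, knockdown and overexpression, and mitochondrially encoded genes -0.39, 0.62 and 0.71. HOXA genes had 0.46 in the knockout and 0.16 in the knockdown. In the order knockout, knockdown and overexpression, medians were 0.20, 0.0037 and 0.028 for collagen genes, -0.046, 0.079 and -0.29 for proteasome subunits, 0.19, -0.029 and -0.015 for zinc finger genes, 0.064, 0.44 and 0.36 for HLA class I and peptide loading, 0.24, -0.062 and 0.40 for aminoacyl-tRNA synthetases, 0.070, -0.00082 and -0.023 for protocadherins, and -0.066, 0.0028 and 0.028 for solute carriers. Ribosomal proteins changed direction with the dye, with medians of 0.19 and -1.10 for the clone in Cy5 and in Cy3 in the knockout, 0.41 and -0.33 in the knockdown and 1.14 and -0.56 in the overexpression.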
